A study of Homo sapiens with 11 samples.

How the data were processed

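Enhanced crosslinking and immunoprecipitation (eCLIP) maps RNA bound to a protein by crosslinking cells with ultraviolet light, fragmenting the RNA, precipitating the protein and sequencing the RNA that comes with it. Here the protein was RPS19, a protein of the small ribosomal subunit, carried as a V5-tagged copy on a transfected plasmid in HEK293T cells, a human embryonic kidney line that expresses the SV40 large T antigen. Per the labels, 11 samples fall into 4 groups. These are 3 replicates each of wild-type RPS19 (WT), the Diamond-Blackfan anemia substitution R62W and size-matched input, and 2 replicates of the substitution R101H. The IP samples came from transfected cells and the inputs from cells without a plasmid, per the labels' protocols. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

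The submitters' processing notes name fastp, STAR and the GRCh38 build. Versions, the window caller and its settings are not given in the sources used here. The authors deposited 1 table of enriched windows and 1 table of repeat elements per IP group, each made from all replicates of the group. Per the file headers, the deposited IP and input counts are whole-number read counts per window or element, summed over replicates. The deposited log2 values are log2 odds ratios of IP over input, given as the lowest, mean and highest over replicates. The deposited p-values and q-values are those of the authors' enrichment test. The fraction of G and C bases per window is also deposited. A further deposited column gives another quantity, the number of replicates in which a window passed. From the values, each listed window had a highest q under 0.2 and passed in at least 2 replicates. The lowest, mean and highest log2 values of a window covered only the replicates in which it passed, while those of repeat elements covered all replicates. Windows that a list leaves out have no value, so absence from a list is not a measured 0. Within bins of G and C content, the log2 odds ratio differed from the log2 ratio of IP to input by a nearly constant amount, so it is relative to a baseline set per bin.

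No total per library is given in the tables. The count behind a listed window was low, with a median pooled IP count of 49 in WT, 47 in R62W and 48 in R101H, and a median pooled input count of 11, 12 and 11. IP counts over listed windows summed to 2414455, 7234584 and 7221756. Those sums grow with the number of windows listed and are not library depths. Because counts were pooled over replicates, no count model could be fitted.

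Window coordinates were written 1-based on GRCh38. Window annotations were grouped into coding sequence, 3′ UTR, 5′ UTR, intron (splice site windows included), lncRNA exon and other. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and differences of shares carry 95% intervals from 1000 resamples of genes, since windows of a gene are not independent. These intervals do not cover the spread between replicates. Overlap was counted at identical coordinates. With 3 values per group, the lowest, mean and highest fix the remaining one, and with 2 they fix both. These unlabelled replicate values were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) for windows listed in both groups, with Benjamini-Hochberg adjustment at 0.05. On simulated windows with a log2 change of 4, this recovered 73% of changed windows for R62W minus WT, 49% for R101H minus WT and 0% for R101H minus R62W. With a log2 change of 2 it recovered 24%, 6% and 0%. With windows enriched in every replicate the shares were 92%, 91% and 53% for a change of 4, and 69%, 54% and 5% for a change of 2. In windows enriched in every replicate of both groups, the summed input counts of R62W and WT had a ratio of 1.00 and were identical in 79.7% of 2672 windows. Those of R101H were 0.664 times those of WT and identical in 3.41% of 2730 windows, and 0.671 times those of R62W and identical in 2.04% of 34309. Which inputs each list used is not given in the sources used here.

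Before the data were examined, 21 gene lists were fixed: small and large subunit ribosomal proteins, other terminal oligopyrimidine mRNAs, the small subunit processome, late 40S maturation factors, 60S biogenesis factors, translation initiation factors, aminoacyl-tRNA synthetases, SR proteins and hnRNPs, chaperones, integrated stress response genes, p53 target genes, nuclear-encoded oxidative phosphorylation genes, the proteasome, erythroid genes, replication-dependent histones, snoRNA host transcripts, mitochondrially encoded transcripts, snoRNAs with scaRNAs, spliceosomal snRNAs, and RNA polymerase III transcripts with other small RNAs. Each list was tested per group with a two-sided Fisher exact test against the other genes among the 8697 genes listed in any group, adjusted over 63 tests. On simulated lists of 30 genes with odds of 4 in WT, 79% were recovered in 100 runs. Input counts used for matching were summed over a gene's listed windows only. They rise with the number of its listed windows and do not measure the abundance of its RNA alone. For shared windows, each list's median difference was set against 10000 random lists matched on input count, adjusted over 56 tests, and windows were also tested with adjustment over the list alone. RefSeq annotation of GRCh38.p14 matched 7958 of the 8697 genes (91.5%) to a protein-coding gene by name. It gave the protein-coding background of an alternative and the position of the 45S gene.

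Named genes followed a rule fixed beforehand: RPS19; per group the 10 protein-coding and 5 non-coding genes with the highest mean enrichment and the 5 genes with most windows; per pair of groups up to 10 genes each way among windows past the threshold; the 5 genes with most windows in 1 list and none in another; 3 members per gene list; and the 10 repeat elements with the highest mean plus tRNA and other small RNA families. Examples among these are given. Other genes named were chosen after their values were seen.

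Alternatives were a highest q of at most 0.05, a mean log2 odds ratio of at least 1, windows enriched in every replicate, a pooled IP plus input count of at least 50, 1 window per gene, lists of equal length, windows extended by 100 bases, matching on input count, a protein-coding background, all 3 IP groups in 1 limma fit, centring on the median difference, a variance trend on count, and Fisher's exact test of pooled IP counts. Lists of equal length kept the windows with the highest mean log2 odds ratio, up to the length of the WT list. A few alternatives were added after seeing the data. Motif counts need a genome sequence and were not made. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.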

Results

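RNA bound by V5-tagged RPS19 was compared between the wild-type protein and the Diamond-Blackfan anemia substitutions R62W and R101H in HEK293T cells, with 3 WT, 3 R62W and 2 R101H immunoprecipitates and 3 size-matched inputs. The enriched windows of each group were listed from all of its replicates, and enrichment values are the authors' mean log2 odds ratios over input, with the lowest and highest replicate in which the window passed. The comparisons address how each substitution alters the RNA recovered with RPS19.

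RPS19 itself was enriched in all 3 groups, mainly over its coding sequence. The median log2 odds ratio of its coding windows on chromosome 19 was 5.20 over 6 windows in WT, 5.05 over 7 in R62W and 4.84 over 7 in R101H. Its 3′ UTR windows had medians of 1.82 over 6 windows in WT and 1.66 over 2 in R62W, and none was listed in R101H. They held 59 and 18 pooled input counts in WT and R62W, against 4721 and 4726 in coding windows. The RPS19 window with the highest value in WT and R101H lay beside a splice site in an intron (chromosome 19, 41860675 to 41860774, GRCh38), at 6.53 (6.19 to 7.16) in WT, 6.15 (5.67 to 6.70) in R62W and 6.89 (6.84 to 6.93) in R101H. EEF1A1, which encodes the elongation factor eEF1A1, had 11 windows annotated as 5′ UTR (chromosome 6, 73520027 to 73521032) with medians of 7.93 in WT, 7.58 in R62W and 6.46 in R101H. No EEF1A1 window in coding sequence or 3′ UTR was listed. RPS19 and EEF1A1 held 12.4% and 22.6% of the listed IP counts in WT, 3.50% and 5.76% in R62W, and 2.5% and 2.52% in R101H. These shares are over listed windows and go down as a list grows. The coding IP counts of RPS19 were 281119 in WT and 235859 in R62W over 3 libraries each and 167403 in R101H over 2. The IP cells carried an RPS19 plasmid and the input cells did not, so these values do not measure binding to the cells' own RPS19 mRNA alone.

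**Figure D1:**
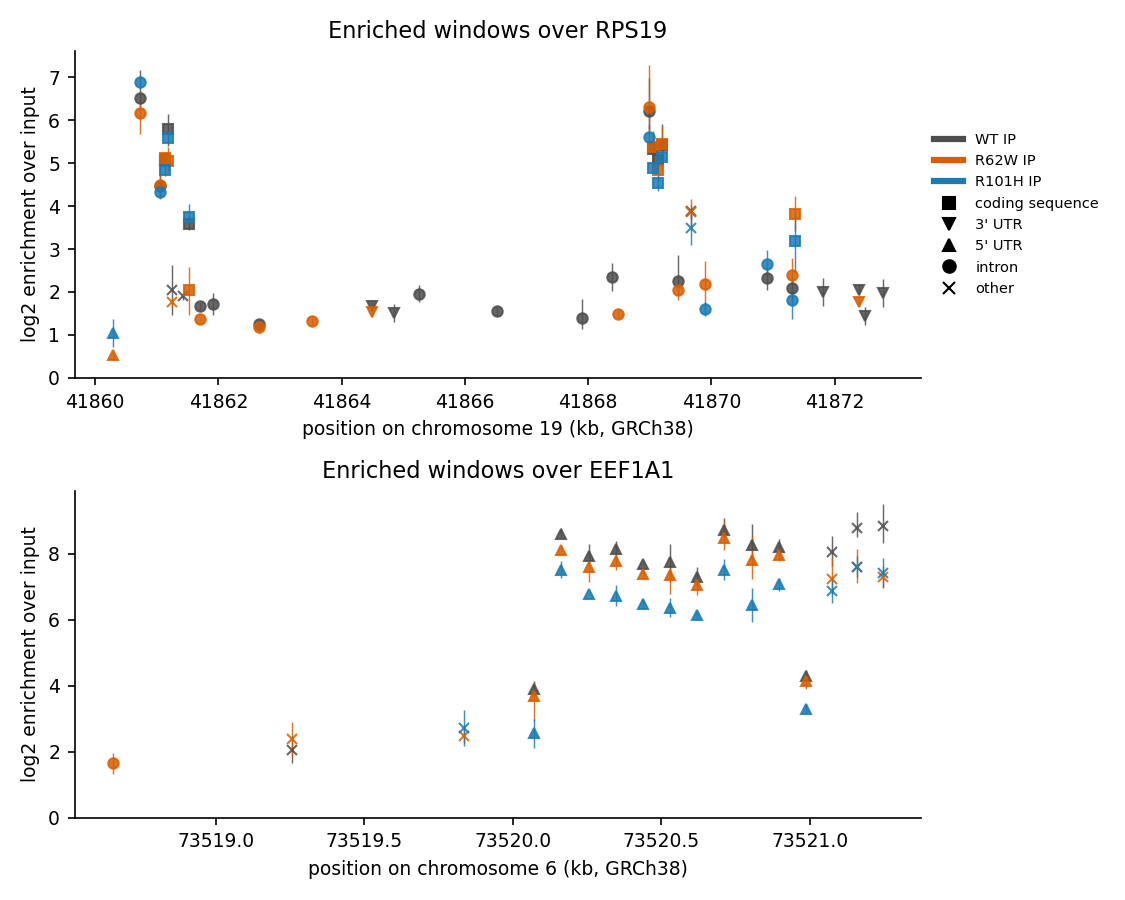
Enriched windows over RPS19 and EEF1A1, with genomic position in kb on the horizontal axis and the authors' mean log2 odds ratio over input on the vertical axis; bars run from the lowest to the highest passing replicate, colours are IP groups and symbols are annotations. RPS19 coding windows have medians of 5.20 in WT, 5.05 in R62W and 4.84 in R101H, and EEF1A1 5′ UTR windows have medians of 7.93, 7.58 and 6.46.

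The substitutions gave longer lists than WT. WT had 15402 enriched windows in 3307 genes, R62W had 86567 in 7780 genes and R101H had 93331 in 8133 genes, which is 5.62 and 6.06 times the WT number of windows. The genes with most windows in the substitution lists, a ranking that favours long transcripts, included MDN1 and HUWE1. MDN1, an ATPase of 60S subunit assembly, had 48 windows in WT, 201 in R62W and 208 in R101H, and the ubiquitin ligase gene HUWE1 had 75, 198 and 204. MACF1, a cytoskeletal crosslinker, had 45, 198 and 204, MYCBP2 had 97, 195 and 190, HERC2 had 87, 182 and 184, and PRRC2B had 93, 206 (86 intronic) and 166. In WT the genes with most windows were GSE1 with 170 (167 intronic), the miR-34a host gene MIR34AHG with 131 (120 intronic), CSNK1E with 112 (95 intronic), LMNA with 108 and PI4KAP2 with 103 (89 intronic). LMNA, which encodes lamins A and C, had 33 windows in R62W and 4 in R101H, GSE1 had 78 and 70, MIR34AHG had 34 and 36, CSNK1E had 113 and 76, and PI4KAP2 had 75 and 47. Windows enriched in every replicate numbered 3516 (22.8%) in WT and 38502 (44.5%) in R62W, or 11 times as many in R62W. With a highest q of at most 0.05, the lists of R62W and R101H were 7.57 and 14.4 times as long as that of WT. The highest q covers up to 3 passing replicates in WT and R62W and 2 in R101H, so this cut was less strict for R101H. The lists are 1 per group, so their lengths carry no test between groups.

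Beside EEF1A1, whose highest window had 8.84 in WT, intronic windows of a few genes had the highest enrichments. A window in an intron of PRKCA, the gene of protein kinase C alpha (chromosome 17, 66757027 to 66757126), had 9.14 (7.99 to 10.11) in WT, 10.30 (8.71 to 12.31) in R62W and 9.81 (8.95 to 10.66) in R101H, with pooled input counts of 1, 1 and 0. Intronic windows of the transcription factor gene ETV5 had 8.76, 10.02 and 8.93, and those of the keratin gene KRT19 had 8.16, 9.26 and 8.40, with an input count of 0 in each list. UBTD2 had 7.06, 8.29 and 7.67, NBN had 7.06, 7.72 and 6.38, WWP2 had 6.63, 7.32 and 6.55, and PSTPIP2 had 6.54, 7.23 and 6.64. Among non-coding genes, the U2 pseudogene RNU2-5P had 4.77, 6.19 and 5.58, the U3 copy SNORD3E had 5.45, 5.57 and 3.72, and the pseudogene PKD1P6 had 3.42, 5.31 and 5.33. An input count near 0 leaves the size of such a ratio poorly fixed. Reads of NBPF, PKD1 pseudogene, NPIP, U2 and U3 copies can map to several near-identical loci, so their positions are uncertain.

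Some genes had many windows in the substitution lists and none in WT. ADCY1, an adenylyl cyclase gene, had 77 windows in R62W and 93 in R101H, and GOLGA4 and NUP98 each had 38 and 40. KIAA1671 had 37 and 44, ADGRV1 had 32 and 61, MYO9A had 32 and 49, and the inositol trisphosphate receptor gene ITPR3 had 31 and 47. In the other direction, the lncRNA RP11-875O11.1 had 10 intronic windows in WT and none in either substitution. CD55 had 13 windows in WT and 3 in R62W, TNFRSF12A had 6 and 1, and CTB-25B13.5 had 5 and 3, with none listed in R101H. BASP1 had 4 windows in WT and AJUBA had 2, with none in R62W. Between the substitutions, L3MBTL3, PDLIM1 and ZCCHC2 had 8 windows each in R101H and none in R62W, and GPR89B had 5 in R62W and none in R101H.

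Coding sequence took a larger share of the windows in both substitutions, and introns took a larger share in WT. Coding windows made up 35.8% of the WT list, 53.2% of the R62W list and 53.7% of the R101H list. Intronic windows made up 31.4%, 13.5% and 10.7%. The coding share was 17.4 percentage points higher in R62W than in WT (gene-resampled 95% interval 15.1 to 19.6) and 17.9 higher in R101H (15.5 to 20.2). The R62W minus WT difference of the intronic share was -17.9 (-20.9 to -14.9) and that of R101H minus WT was -20.7 (-24.0 to -17.5). The 3′ UTR share was 21.4% in WT, 23.2% in R62W and 26.3% in R101H, and 5′ UTR shares were 3.49%, 4.03% and 3.88%. The R101H minus R62W differences were 0.57 (0.22 to 0.93) for coding and -2.76 (-3.10 to -2.43) for intronic windows. Those between the substitutions changed sign, to -1.72 and 1.64, among windows enriched in every replicate, and the coding difference was -1.33 with 1 window per gene. Every listed R101H window passed in both replicates, so the every-replicate filter shortened the R62W list and left that of R101H whole. The R101H minus R62W differences were 4.32 and -8.05 with lists of equal length. With lists of equal length, the R62W minus WT differences shrank to 4.37 for coding and -4.38 for intronic windows and those of R101H minus WT to 8.69 and -12.4, and with 1 window per gene they were 4.71 and -4.75 for R62W and 3.38 and -7.94 for R101H.

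**Figure D2:**
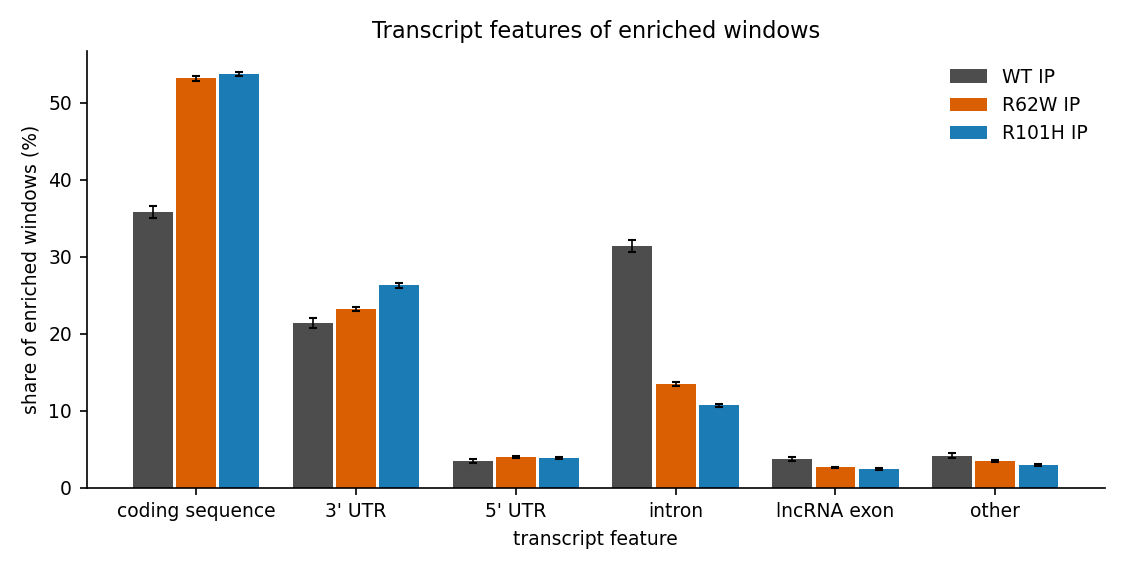
Share of enriched windows in percent (vertical axis) by transcript feature (horizontal axis) for WT, R62W and R101H; error bars are exact Clopper-Pearson 95% intervals, which cover counting error only. Coding sequence holds 35.8%, 53.2% and 53.7% of windows and introns hold 31.4%, 13.5% and 10.7%.

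Most WT windows recurred in the substitution lists. R62W shared 12263 windows with WT (79.6% of WT, 79.0 to 80.3) and R101H shared 11082 (72.0%, 71.2 to 72.7), while R62W and R101H shared 59874 (69.2% of R62W, 68.9 to 69.5). With lists of equal length these shares were 25.4%, 24.2% and 47.7%. Independent lists of these lengths would share about 4736, 5106 and 28700 windows among 281516 tested, a lower bound if the authors' q is a Benjamini-Hochberg value. That expectation gives each tested window the same chance of being listed, whatever its read count. An excess over it is therefore not by itself a shared effect. In windows enriched in every replicate of both groups, the summed input counts of R62W and WT had a ratio of 1.00, while those of R101H were 0.664 times those of WT and 0.671 times those of R62W, so which inputs the R101H list used is not known. In 20 simulations of unchanged groups against shared inputs 0 windows were called, which leaves the overlap due to shared inputs unmeasured. Part of the excess over independent lists may come from shared inputs, whose libraries could not be split. Of the 2684 windows listed in WT alone, 84.2% were intronic (82.8 to 85.6). Of the 49247 windows shared by both substitutions and not listed in WT, 58.2% were coding and 7.62% intronic. Both substitutions had windows in 4011 genes without a WT window, and 17 genes had windows in WT alone.

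Among windows listed in both R62W and WT, no window passed the threshold in limma. Of 12263 windows tested, 0 had an adjusted p under 0.05 and 1252 had an unadjusted p under 0.05, while Fisher's exact test on pooled IP counts, which compares the pooled libraries only, called 1632 of 2672 windows. The median difference over all 12263 windows, R62W minus WT, was 0.26. By feature it was 0.33 (gene-resampled 95% interval 0.29 to 0.37) for coding windows, 0.36 (0.33 to 0.38) for 3′ UTR windows and -0.09 (-0.15 to -0.04) for intronic windows. Values cover passing replicates only, and 22.8% of listed WT windows and 44.5% of listed R62W windows passed in every replicate. Replicates were thus left out more often in WT, which these intervals do not cover. When limited to the 2672 windows enriched in every replicate, limma called 1 window, in an intron of the sorting nexin gene SNX6 (chromosome 14, 34568910 to 34569008). Its log2 odds ratio was 8.15 (7.93 to 8.27) in R62W and 4.05 (3.35 to 4.55) in WT, a difference of 4.11 (SE 0.37, limma adjusted p = 0.024). The median difference over these 2672 windows was 0.57. With each difference centred on it, a setting added after seeing the data, limma called 0 of them (lowest adjusted p = 0.0647), with 244 at an unadjusted p under 0.05.

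The same comparison for R101H and WT called 0 of 11082 windows in limma, with 2365 at an unadjusted p under 0.05 and 2106 of 2730 called by Fisher's exact test on pooled counts. Over all 11082 windows the median difference was 0.60. It was 0.63 (0.58 to 0.70) for coding windows, 0.80 (0.77 to 0.82) for 3′ UTR windows and 0.03 (-0.05 to 0.11) for intronic windows. Here too, replicates that did not pass were left out in WT, while no replicate was left out in R101H. Among the 2730 windows enriched in every replicate, limma called 498, of which 487 in 216 genes were higher in R101H and 11 in 8 genes were lower. The higher windows had a median difference of 1.61 and included 208 coding, 171 3′ UTR and 13 intronic windows. Examples were an adjacent intronic SNX6 window (difference 4.37, SE 1.13, limma adjusted p = 0.0489) and the 3′ UTR of SBF1 (2.52, SE 0.55, limma adjusted p = 0.0456). Others were the 3′ UTR of AGAP3 (2.43, SE 0.60, limma adjusted p = 0.0469) and the stop codon window of HERC2 (2.42, SE 0.40, limma adjusted p = 0.0456). This SNX6 window had 7.13 in R101H, 2.76 in WT and 3.32 in R62W. The SNX6 window called for R62W had 3.61 in R101H and 4.05 in WT, so the substitutions did not share a called SNX6 window. Of 5 SNX6 windows shared by R101H and WT, 3 were lower in R101H, with a median difference of -0.44. The lower windows included an intron window of BBC3, which encodes the pro-apoptotic protein PUMA, at -1.60 (SE 0.35), and CDKN1A, the gene of the cell cycle inhibitor p21, at -1.77 (SE 0.45). They also included the U3 genes SNORD3A at -1.47 (SE 0.34) and SNORD3B-2 at -1.27 (SE 0.33), the MIR6724-1 region at -2.31 (SE 0.37) and an EEF1A1 5′ UTR window at -1.42 (SE 0.37), with limma adjusted p-values of 0.0456 to 0.0494. The median difference over these 2730 windows was 0.91. After each difference was centred on it, limma called 0 of the same 2730 windows, with 444 at an unadjusted p under 0.05. This last setting was added after seeing the data.

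Between the substitutions, limma called 0 of 59874 windows, with 1076 at an unadjusted p under 0.05, and Fisher's exact test on pooled counts called 929 of 34309. In simulated data this fit recovered 0% of windows changed by a log2 of 4, so its count of 0 says nothing about differences of that size. Among the 34309 windows enriched in every replicate, limma also called 0. In simulated data that fit recovered 53% of windows changed by a log2 of 4 and 5% of those changed by 2. The median R101H minus R62W difference was 0.21, at 0.21 (0.20 to 0.22) for coding, 0.28 (0.27 to 0.29) for 3′ UTR and 0.06 (0.04 to 0.08) for intronic windows. Replicates that did not pass were left out in R62W only.

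Windows of U3 snoRNA genes had lower values in R101H than in WT and R62W. U3 guides early 18S rRNA processing. Windows of U3 genes had a median of 2.43 over 15 windows in R101H, 3.18 over 24 in WT and 3.75 over 25 in R62W, which are different sets of windows. In WT, windows with under 100 pooled input counts held 3772 of the 139918 U3 IP counts. Of the 15 R101H windows, 14 had under 100 input counts, so the lower values rest mostly on sparse windows. The U3 repeat element was listed in WT alone, so it gives no value for either substitution. Of the 15 windows shared with WT, 14 were lower in R101H, with a median difference of -1.10, and 14 of the 15 shared with R62W were lower, with a median difference of -1.57. In the snoRNA list, 5 of 14 shared windows passed for R101H minus WT and 8 of 14 for R101H minus R62W when limma p-values were adjusted over the list alone, against 0 over all windows. The list's median over genes was -1.45 for R101H minus WT, where matched lists had a median of 0.49, and -1.75 for R101H minus R62W, where matched lists had 0.13 (permutation adjusted p = 0.00224 for both, from 0.0002, the smallest p these permutations can give). The list of RNA polymerase III transcripts and other small RNAs holds the same U3 genes and had the same medians, against 0.48 and 0.13 in matched lists. Spliceosomal snRNA windows had a median difference of -0.49 for R101H minus R62W over 13 genes, against 0.17 in matched lists (permutation adjusted p = 0.00224), and 0.09 for R101H minus WT over 10 genes, against 0.54 (permutation adjusted p = 0.0207). Most of these genes are near-identical copies or pseudogenes, so they are not independent of each other.

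Small RNA genes had a window in R101H less often than other genes did, while differences between the groups were not tested. Of 23 genes in the RNA polymerase III and small RNA list, 6 (26.1%) were listed in R101H, 22 (95.7%) in R62W and 11 (47.8%) in WT. Of 36 spliceosomal snRNA genes, 16 (44.4%), 35 (97.2%) and 18 (50%) were listed, and of 26 snoRNA and scaRNA genes, 15 (57.7%), 22 (84.6%) and 16 (61.5%). The R101H shares were below those of other genes by Fisher's exact test (adjusted p = 2.22e-14, 1.08e-13 and 3.08e-06) and below those of genes matched on input count (permutation adjusted p = 0.00252 for each). Many of these genes are near-identical copies or pseudogenes, and the U3 genes are in both the small RNA and the snoRNA list. The tests count each copy as an independent gene, so these p-values overstate the evidence. Against matched genes, the spliceosomal snRNA share was higher in WT (25.8% in matched genes, permutation adjusted p = 0.00252) and in R62W (77.6%, permutation adjusted p = 0.021), without passing Fisher's exact test (adjusted p = 0.367 for both). Mitochondrially encoded transcripts had 9 of 9 genes listed in WT, 4 of 9 in R62W and 8 of 9 in R101H. The R62W share was lower than that of other genes (Fisher's exact adjusted p = 0.00791) and of matched genes (permutation adjusted p = 0.00252). It no longer passed Fisher's exact test at a mean log2 of at least 1, which left 3 of these genes in any list (adjusted p = 0.178), or among windows enriched in every replicate (adjusted p = 0.0942). MT-ND4 had 3 windows in WT, 0 in R62W and 4 in R101H.

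p53 target genes were listed in WT more often than other genes. Of 17 genes, 15 (88.2%) had a WT window, against 37.9% of other genes (Fisher's exact adjusted p = 0.000251). Among genes matched on input count over listed windows it was 60% (permutation adjusted p = 0.0252). All 17 were listed in R62W and in R101H, where 89.4% and 93.5% of other genes were listed. Against shares that high, a list with every gene listed may not pass, so a higher call in WT alone does not make a list particular to WT. CDKN1A had 77 windows in WT (55 intronic), 54 in R62W and 39 in R101H, BBC3 had 72 (58 intronic), 53 and 43, and the ferredoxin reductase gene FDXR had 74 (58 intronic), 54 and 61. MDM2, which encodes a ubiquitin ligase of p53, had 19, 59 and 62. The 17 genes together had 373 windows in WT, 395 in R62W and 409 in R101H. The median difference over their shared windows was -0.13 for R62W minus WT, against 0.25 in matched lists (permutation adjusted p = 0.0042), and 0.00 for R101H minus WT, against 0.55 (permutation adjusted p = 0.00747).

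Other lists were also higher in WT than other genes but did not keep the call against genes matched on input count. These input counts cover listed windows only, so they are not RNA abundance. SR proteins and hnRNPs had 31 of 35 genes listed (88.6%, Fisher's exact adjusted p = 1.56e-08, 86.3% in matched genes, permutation adjusted p = 1), with PTBP1 at 53 windows in WT, 78 in R62W and 52 in R101H. Chaperones had 29 of 35 (82.9%, adjusted p = 1.84e-06 by Fisher's exact test, 67.6% in matched genes, permutation adjusted p = 0.19), with HSPA8 at 15, 19 and 17 windows. Nuclear-encoded oxidative phosphorylation genes had 34 of 50 (68.0%, Fisher's exact adjusted p = 0.000251, 55.9% in matched genes, permutation adjusted p = 0.258), with SDHA at 8, 16 and 22 windows. Large subunit ribosomal protein genes had 28 of 47 (59.6%, Fisher's exact adjusted p = 0.0233), below the 60.9% of matched genes (permutation adjusted p = 1), with RPL3 at 3, 24 and 13 windows. Mitochondrially encoded transcripts had 9 of 9 in WT (Fisher's exact adjusted p = 0.0013, 93.6% in matched genes, permutation adjusted p = 1). By Fisher's exact test, the calls of oxidative phosphorylation and large subunit ribosomal protein genes also ended at a highest q of at most 0.05 (adjusted p = 0.202 and 0.735) and among windows enriched in every replicate (0.595 and 1). At a mean log2 of at least 1, those of large subunit ribosomal proteins and mitochondrially encoded transcripts ended (adjusted p = 0.498 and 0.22). Over shared windows, the R62W minus WT median was -0.03 for chaperones, against 0.23 in matched lists (permutation adjusted p = 0.00373), and 0.02 for large subunit ribosomal proteins, against 0.24 (permutation adjusted p = 0.0179). For mitochondrially encoded transcripts it was -0.39 over 4 genes, against 0.29 (permutation adjusted p = 0.0042). For R101H minus WT, large subunit ribosomal proteins had 0.27, against 0.55, and mitochondrially encoded transcripts had -0.04, against 0.59 (permutation adjusted p = 0.0396 and 0.0207). For R101H minus R62W, small subunit ribosomal proteins had 0.09, against 0.19, and SR proteins and hnRNPs had 0.16, against 0.23 (permutation adjusted p = 0.0207 and 0.0336). In all, 15 of the 56 list differences passed.

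The remaining lists did not pass Fisher's exact test against other genes in any group. In R62W and R101H this test could hardly call a list higher. Chaperones, with 35 of 35 genes listed against 89.4% and 93.5% of other genes, did not pass there (Fisher's exact adjusted p = 0.172 and 0.367). No lists were simulated for these groups. With all protein-coding genes as background, which includes genes with no window in any group, 45 of 51 tests of 17 lists passed, against 5 of the same tests with genes listed in any group as background. In WT, small subunit ribosomal proteins had 17 of 32 genes listed, with RACK1 at 7 windows in WT and 24 in each substitution, and other terminal oligopyrimidine mRNAs had 13 of 20, with EEF1D at 9, 51 and 60. The small subunit processome had 10 of 36, with HEATR1 at 3, 49 and 49 windows. Late 40S maturation factors had 2 of 15, with TSR1 at 0, 27 and 23, and 60S biogenesis factors had 13 of 38, led by MDN1. Translation initiation factors had 22 of 37, with EIF4G1 at 12, 58 and 73 windows. Aminoacyl-tRNA synthetases had 4 of 19, below the 51.7% of matched genes (permutation adjusted p = 0.0378), with QARS1 at 2, 18 and 27. The proteasome had 18 of 30, with PSMD11 at 2, 21 and 17, integrated stress response genes had 7 of 14, with PPP1R15B at 7, 30 and 30, and snoRNA host transcripts had 17 of 31, with EIF4A1 at 13, 32 and 27. Erythroid genes had 2 of 9, with the transferrin receptor gene TFRC at 9, 10 and 15 windows, and replication-dependent histones had 1 of 5, with H4C15 at 0, 2 and 3. With adjustment over the list alone, limma called 3 of the 71 shared windows of 60S biogenesis factors for R101H minus WT.

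**Figure D3:**
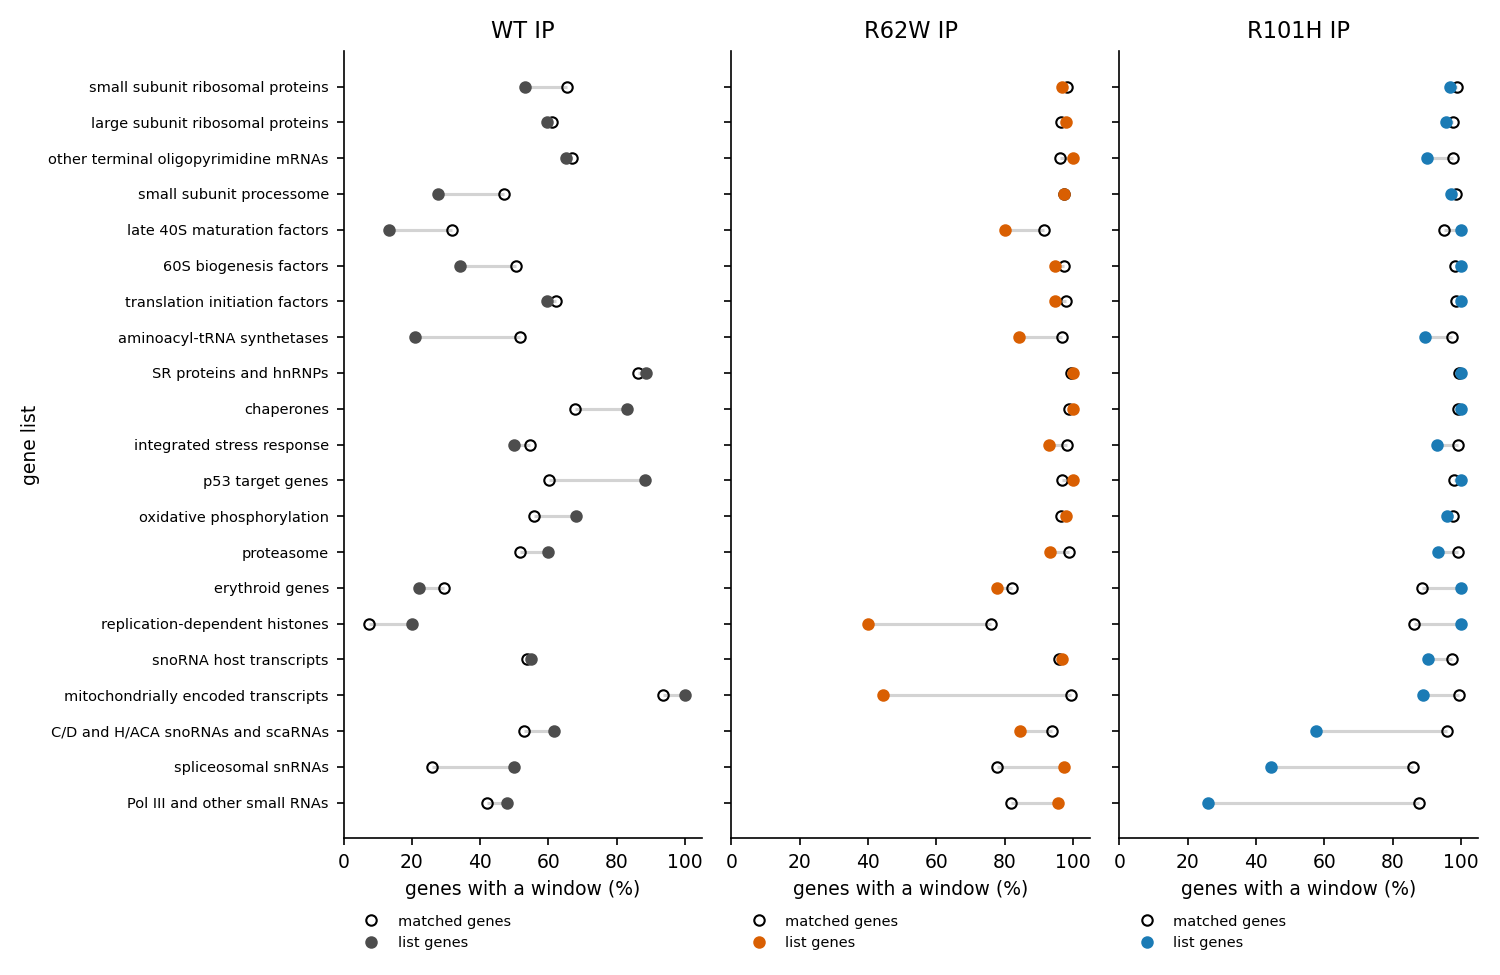
Percent of genes with an enriched window (horizontal axis) for each gene list (vertical axis) in WT, R62W and R101H; filled circles are the genes of the list and open circles are the mean of random lists matched on input count. The p53 target genes reach 88.2% in WT against 60% in matched genes, and RNA polymerase III and other small RNAs reach 26.1% in R101H against 87.8%.

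Among repeat elements other than simple repeats, a tRNA family had the highest mean in each group. tRNA-Thr-ACY had a mean log2 odds ratio of 2.82 (2.00 to 3.76) in WT, 4.02 (3.12 to 5.13) in R62W and 3.39 (2.57 to 4.22) in R101H, and tRNA-Ser-TCY had 1.67, 3.31 and 2.65. The tables listed 34 tRNA families in WT, 51 in R62W and 35 in R101H, with medians of 1.72, 2.27 and 2.30. Of the 34 families shared by R62W and WT, 34 had the higher mean in R62W, with a median difference of 0.89, and 31 of the 32 shared by R101H and WT had the higher mean in R101H, with a median difference of 0.46. Over all shared repeat elements the median differences were 0.59 and 0.45. Relative to those medians, 25 of 34 tRNA families were higher in R62W than in WT, with a median of 0.30, and 16 of 32 in R101H than in WT, with a median of 0.01. By pooled IP counts relative to the shared elements, 23 of 34 were higher in R62W, with a median of 0.21, and 18 of 32 in R101H, with a median of 0.10, while the medians of all elements were -0.09 and 0.06. The tRNA families held 71.8% of these pooled counts in R62W and 67.2% in WT. Of the 35 families shared by R101H and R62W, 3 had the higher mean in R101H, with a median difference of -0.49, and relative to the median of all elements (0.16) 2 were higher, with a median of -0.65. By pooled IP counts 7 were higher, with a median of -0.19, while the median of all elements was 0.30. U7 had 2.51, 3.45 and 2.60, U6 had 1.47, 1.96 and 2.00, and U8 had 0.99, 1.16 and 0.88, while U3 was listed in WT alone at 0.54 (0.27 to 0.76). The simple repeat (CGAGCCG)n fell from 4.69 (4.19 to 5.42) in WT to 2.38 in R62W, a difference of -2.32 (SE 0.36, limma adjusted p = 0.0279) and 1 call of 68 elements tested, with 19 at an unadjusted p under 0.05. No tRNA family passed. For R101H minus WT, limma called 0 of 65 elements, with 5 at an unadjusted p under 0.05 and 51 called by Fisher's exact test on pooled counts. For R101H minus R62W it called 0 of 165, with 7 and 127.

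**Figure D4:**
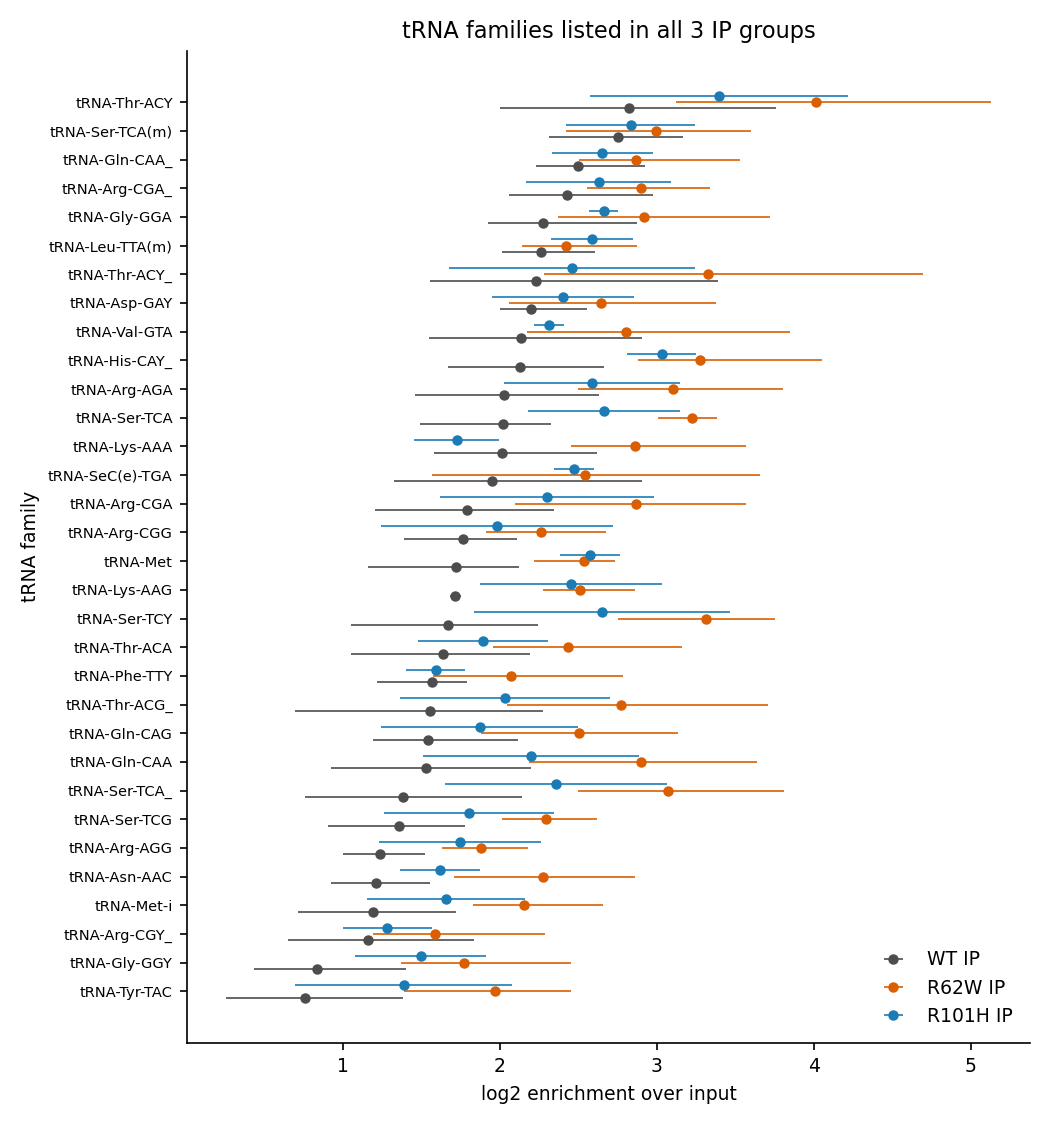
Mean log2 odds ratio over input (horizontal axis) of the 32 tRNA families listed in all 3 groups (vertical axis); bars run from the lowest to the highest replicate. tRNA-Thr-ACY lies at 2.82 in WT, 4.02 in R62W and 3.39 in R101H, and most ranges overlap; relative to the median of all shared elements, 16 of the 32 families are higher in R101H than in WT.

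The G and C content of enriched windows averaged 50.7% in WT, 50.1% in R62W and 49.5% in R101H. The difference was -0.54 percentage points for R62W minus WT (gene-resampled 95% interval -1.01 to -0.09), -1.16 for R101H minus WT (-1.66 to -0.64) and -0.62 for R101H minus R62W (-0.69 to -0.54). With lists of equal length the differences were -1.14, -2.73 and -1.59.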

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

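The tests of explanations in this part were chosen after the results they bear on were seen, although equal list length and the split of RPS19 windows were planned before the data were examined. Differences between the IP groups in the make-up of their lists and in 1 repeat element are given here because the interval of the difference excluded 0 or the test passed.

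For R62W minus WT, the share of windows differed by 17.4 percentage points for coding sequence, 1.82 for 3′ UTR, 0.55 for 5′ UTR, -17.9 for introns, -1.06 for lncRNA exons and -0.74 for other annotations. For R101H minus WT the differences were 17.9 for coding sequence, 4.90 for 3′ UTR, -20.7 for introns, -1.29 for lncRNA exons and -1.25 for other annotations. For R101H minus R62W they were 0.57 for coding sequence, 3.09 for 3′ UTR, -0.157 for 5′ UTR, -2.76 for introns, -0.224 for lncRNA exons and -0.512 for other annotations. The G and C content differed by -0.54, -1.16 and -0.62 percentage points for R62W minus WT, R101H minus WT and R101H minus R62W. The simple repeat (CGAGCCG)n differed by -2.32 on the log2 scale for R62W minus WT.

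The R62W and R101H lists were 5.62 and 6.06 times as long as the WT list. Deeper IP libraries would raise the baseline of IP over input behind the odds ratios, but in windows with at least 100 pooled input and IP counts it differed from WT by a median of -0.0954 for R62W (236 windows) and 0.0176 for R101H (139 windows). With at least 50 input counts the R101H median was 0.0257 over 369 windows with a central 95% of -0.103 to 0.215, a range adopted after a single window had been seen to reach 0.582, and both values argue against depth as the cause. If the authors' q is a Benjamini-Hochberg value, p over q at the cutoff approximates the share of windows a replicate called. Here the highest p was divided by the highest q in windows with a highest q near 0.2. Over such WT windows the ratio ran from 4.27% to 13.2%, with a median of 10.8%. The highest p and q can come from different replicates, so these are not values of single replicates. The highest WT ratio lay below the lowest R62W ratio, at 25.1%. Under that assumption this argues against a single weak WT replicate as the whole cause. A difference in the RNA that the substituted proteins bind, and a difference in the amount of tagged protein, both stay open and were not tested.

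Introns held a larger share of the WT list, and p53 target genes held many of its windows. With the longer lists cut to the WT length by highest mean log2 odds ratio, the R62W minus WT intron difference was -4.38 percentage points (-7.37 to -1.17) of -17.9. That of R101H minus WT was -12.4 (-15.9 to -8.77) of -20.7. In R62W, intronic windows had a higher median log2 odds ratio than coding windows (2.30 against 1.82), so this cut favours introns. It does not settle how much of the difference list length alone would give. A few intron-rich genes could not account for the whole difference, since R62W minus WT was -11.7 (-13.9 to -9.89) without the 20 genes that held 31.2% of WT intron windows. More RNA from p53 target genes in transfected cells than in the input might give windows in all 3 groups alike. The R62W list held 1.06 times the WT number in these genes, against 5.62 times over all genes. Single genes were not alike: CDKN1A, BBC3, FDXR and PHLDA3 had fewer windows in R62W than in WT, and the rest had as many or more. Of the shared windows of CDKN1A, BBC3 and FDXR, 43 of 53, 36 of 47 and 41 of 47 were lower in R62W, with medians of -0.64, -0.43 and -0.35. More RNA from these genes cannot be told apart from binding by RPS19, because every IP and no input came from transfected cells, and large T antigen binds p53 in this line.

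Windows over the 5′ end of EEF1A1 and the coding sequence of RPS19 were among the most enriched. RNA from the expression plasmid is a candidate source: RPS19 coding windows lay 3.37 above its 3′ UTR windows in WT. Those 3′ UTR windows held 59 pooled input counts, against 4721 in coding windows. Those at 41864446 to 41864536 and 41864809 to 41864899 lie between coding windows. They may therefore not be the 3′ UTR of the transcript that holds the coding windows, which limits this contrast. Intronic windows beside splice sites, at 6.53 and 6.22, lay above its coding windows, on pooled input counts of 45 and 61. The second of these directly borders a coding window. In WT, RPS19 intron windows held 14576 IP counts and coding windows 281119, so these ratios do not decide about plasmid RNA. The EEF1A1 promoter and first intron are common in expression plasmids, but the labels name no promoter. Of the listed EEF1A1 IP count in WT, 91.6% lay in 5′ UTR windows. Exon windows directly upstream of these, at 73521033 to 73521287, held 20123, 18004 and 7913 IP counts in WT at 8.06, 8.77 and 8.84. No coding or 3′ UTR window of EEF1A1 was listed. Without the plasmid sequence, plasmid RNA cannot be told apart from local binding to the cells' own EEF1A1 RNA.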

How the results depend on the processing

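The alternatives without the 20 genes richest in WT intron windows, with centring among windows enriched in every replicate, and with windows per gene in WT over another list were chosen after seeing the data. No paired analysis was possible because the labels share replicate numbers but the deposited columns carry none. For the same reason no replicate was left out in turn and no other splits of the R62W and WT samples were run. Pooled input counts near 10 per window limit the precision of single windows. Of 182 alternative values, 77 for the comparisons and 42 for single gene lists kept their direction and their side of the threshold, and a further 12 for single lists no longer passed. Where a filter changed a list's length, fewer windows are the construction of that filter; for the other changes below the cause was not tested.

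With a highest q of at most 0.05, WT had 2987 windows, R62W 22616 and R101H 43148, a cut over up to 3 replicates in WT and R62W and 2 in R101H. Windows enriched in every replicate numbered 3516 in WT and 38502 in R62W. That filter left all 93331 R101H windows, since each had passed in both replicates, so comparisons under it set shortened lists against a whole one. A pooled count of at least 50 left 9351, 51102 and 55670 in WT, R62W and R101H.

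Of 42 feature share differences, 37 kept their direction and call, though not their size. Over the alternatives, R62W minus WT ran from 4.37 to 29.0 for coding and from -27.2 to -4.38 for intronic windows, and R101H minus WT from 3.38 to 27.2 and from -25.6 to -7.94, smallest in size with equal list length for R62W and with 1 window per gene for R101H. The R101H minus R62W coding difference was -1.72 percentage points among windows enriched in every replicate, -1.33 with 1 window per gene, 0.284 with a count of at least 50 and 0.338 without the 20 genes. The intron difference was 1.64 among windows enriched in every replicate.

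The share of WT windows also listed in R62W was 68.9% at q of at most 0.05, 78.6% at a log2 of at least 1, 76.0% for windows enriched in every replicate, 86.0% at a count of at least 50, 25.4% with equal list length and 88.2% with windows extended by 100 bases. For R101H it was 71.0% at a log2 of at least 1, 77.6% for every replicate, 81.6% at a count of at least 50, 24.2% with equal length and 82.4% with extended windows. The share of R62W windows listed in R101H was 75.5% at q of at most 0.05, 68.6% at a log2 of at least 1, 89.1% for every replicate, 76.6% at a count of at least 50, 47.7% with equal length and 86.1% with extended windows.

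For R62W minus WT, limma called 1 window each among windows enriched in every replicate, with a pooled count of at least 50 and with a variance trend on pooled count. For R101H minus WT it called 498 among windows enriched in every replicate and 154 with the trend. Both counts for windows enriched in every replicate became 0 with centring. Fisher's exact test of pooled IP counts called 1632 windows for R62W minus WT, 2106 for R101H minus WT and 929 for R101H minus R62W. Among repeat elements it called 57, 51 and 127. For repeat elements of R101H minus WT, limma called 2 with all 3 IP groups in 1 fit and 3 with a variance trend on pooled count.

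With all protein-coding genes as background, 45 of 51 gene list tests passed, and 20 passed for windows per gene in WT over another list. Matched on input count, the large subunit ribosomal proteins in WT lay -1.31 percentage points from matched genes. The median log2 odds ratio of RPS19 was 5.20, 5.05 and 4.84 in WT, R62W and R101H over coding windows only, and 1.77 and 2.65 in R62W and R101H over untranslated and intron windows.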

Other observations

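The region and the input limit in this part were chosen after their values were seen, and the counts of lower windows given here carry no test. Upstream of the 45S ribosomal RNA gene, the MIR6724-1 region (chromosome 21, 8205215 to 8205940) ended 48 bases before RNA45SN2, which starts at 8205988 in RefSeq. It had 8 windows in WT at 2.32 to 5.01, with 1816 IP and 54 input counts, 6 in R62W with 426 IP and 42 input counts, and 1 in R101H with 40 IP and 3 input counts. The 6 windows shared by R62W and WT were all lower in R62W, with a median difference of -1.93. The simple repeat (CGAGCCG)n, lower in R62W than in WT, has a G and C content of 0.818. Near-identical 45S copies share these reads, so the copy of origin is unknown.

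The values of shared windows are given next for the 5 genes with most windows in WT. Of 28 LMNA windows shared by R62W and WT, 27 were lower in R62W, with a median difference of -0.84. Of 22 shared GSE1 windows, 18 were lower, with a median of -0.63, and of 25 shared MIR34AHG windows, 22 were lower, with a median of -0.41. Of 70 shared CSNK1E windows, 54 were lower, with a median of -0.25, and of 35 shared PI4KAP2 windows, 19 were lower, with a median of -0.04. For R101H minus WT, 3 of 3 LMNA, 7 of 9 GSE1, 19 of 26 MIR34AHG, 14 of 33 CSNK1E and 6 of 18 PI4KAP2 windows were lower in R101H, with medians of -2.01, -0.95, -0.28, 0.09 and 0.28. For R62W minus WT, over all shared intronic windows the median was -0.09.

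U3 windows with under 100 pooled input counts were lower in R101H than in WT in 14 of 14 shared windows, with a median difference of -1.18, and lower than in R62W in 14 of 14, with a median of -1.64. In R62W, 1 of 19 such windows was lower than in WT, with a median difference of 0.47. The U3 copies share reads, so these windows do not count as independent.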
